A study of Mus musculus with 6 samples.

How the data were processed

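Total RNA from MLL-AF10 leukemia cells of the mouse was labelled with biotin as sense-strand target by a whole-transcript assay and read on Affymetrix arrays, per the labels' protocols. There were 6 arrays, 3 of cells given vehicle and 3 of cells given 0.5 µM of an IKK inhibitor. Each sample's group was taken from its treatment label and its replicate number from its title. The deposited table holds 35512 probe sets with a value on each array. The authors made these intensity values with Affymetrix Expression Console, per the submitters' processing notes; its version and the summarization algorithm are not given in the sources used here. The deposited values ran from 0.71 to 8185.74 with a median of 118 and were therefore read as intensities on a linear scale. Whether they were background-corrected or normalized between arrays by the authors is not stated; array medians lay between 112 and 124 and array means between 445 and 460.2, so no further scaling was applied in the main setting. The table holds no detection calls, so no probe set was judged to be above or below background.

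Values below 16 were set to 16, which 5.95% of all values met, and log2 was taken. The plan had allowed for deposited log2 values; because they were linear, the floor was chosen once the distribution of the values and the spread within groups, but not the differences between groups, had been seen. Fold changes of dim genes are understated by the floor. Probe sets were named through the platform's annotation, which gave 1 gene symbol for 21789, several for 1621 and listed 12102 not at all. Symbols were updated through Entrez gene numbers, which matched for 21698 of the 21789. Probe sets with several symbols and unlisted probe sets were left out of gene results. Of the 19938 genes with a symbol, 999 had more than 1 probe set, and the probe set with the highest mean over all 6 arrays was used. Among 992 of these with several tested probe sets, none had probe sets called in opposite directions. The 91 genes at the floor on all 6 arrays were not tested, leaving 19847. The values of 706 rows were the same as those of another row of the table.

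Inhibitor and vehicle arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates), with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p under 0.05. SE of single genes and 95% intervals are those of the fit. SE of list medians were taken from the spread between the genes of a list. They treat these genes as independent and do not hold the spread between arrays. Means and SD of intensity are of the deposited values. Groups of genes were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over 32 lists; camera with the correlation estimated from the arrays and limma's fry were alternatives. The test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover HOXA and other MLL fusion targets, the MLL complex, NF-kB targets and signalling, interferon, MHC class II, monocyte, neutrophil, progenitor, T cell, B cell, erythroid, mast cell, megakaryocyte, dendritic and stromal markers, the cell cycle, apoptosis, p53, MYC, stress responses, cholesterol, glycolysis, immediate early genes, STAT5, housekeeping and mitochondrial genes. Some genes belong to more than 1 list. A further 14 families were added after the data were seen and are reported only among the additional observations.

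Genes named in the text were, by rule, the 12 largest rises and 12 largest falls among genes past the threshold whose 3 arrays of a group all lay above the 3 of the other, leaving out predicted genes; 28 fixed genes of the fusion, its targets, NF-kB and myeloid cells; and up to 4 members of each list with the smallest p. Of the 28 fixed genes 3 are not analysed here. Any other gene is said to have been named after its value was seen.

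The alternatives were the replicate number as a block, quantile normalization, centring of each array on its median, filters on dim genes at the 25th percentile and the median of intensity, the mean of a gene's probe sets, every probe set tested singly, an intensity trend with a robust prior, array weights, other thresholds, the other list tests, and leaving out each array in turn. Floors of 1, 32 and 64 and the log2 of intensity plus 16 were added after the data were seen. The fit was tested on simulated arrays with the means and spread of the 19847 genes. It recovered 51 of 100 genes changed by 0.5 and 93 of 100 changed by 1 on the log2 scale, with 7 other genes called (4.52% of calls). A simulated list of 30 genes shifted by 0.3 was recovered and 0 unchanged lists were called. The simulated genes varied independently of each other, so this does not show how often camera calls unchanged lists of correlated genes. Only 200 single genes and the 30 of the list were changed, a smaller share than the 13.9% called in the data. The share recovered may therefore differ in the data. The number of arrays limits the precision, and the labels give no batch or date. Figures were drawn with matplotlib 3.10.9.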

Results

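Transcript levels were measured in a mouse leukemia cell line that carries the MLL-AF10 fusion, in which the histone methyltransferase MLL (Kmt2a) is joined to AF10 (Mllt10). RNA from 3 samples of cells given vehicle and from 3 samples of cells given 0.5 µM of an IKK inhibitor was read on 6 whole-transcript arrays. IKK kinases phosphorylate the IkB proteins that hold NF-kB transcription factors in the cytoplasm. The compound's name and the treatment time are not given in the sources used here. The arrays were alike in brightness, with median intensities between 112 and 124. Correlations of log2 values across the genes tested lay between 0.993 and 0.997 for arrays of the same group and between 0.988 and 0.991 for arrays of different groups. Whether the 3 samples of a group came from separate cultures is not stated, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

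The largest changes with the IKK inhibitor, given here gene by gene, were rises of Clec4n, Fpr-rs4 and Marco and falls of Mpo, Rtp4 and Oasl2. The largest rise was that of Clec4n, which encodes the fungal pattern receptor dectin-2. Its intensity was 238 ± 26.6 with vehicle and 1762 ± 72.8 with the inhibitor (SD, n = 3 each), a log2 fold change of 2.89 ± 0.09 (SE). Marco, a scavenger receptor of macrophages, rose by 2.69 ± 0.12 on the log2 scale, from 95.3 to 616. The formyl peptide receptor gene Fpr-rs4 rose by 2.75 ± 0.17 from a low level of 27.0, and as a member of a cluster of similar genes it is reported as uncertain. The other rises among the 12 largest were those of Bhlhe41 (log2 fold change 2.39), the complement factor gene Cfb (2.31), Treml4 (2.23), the RNA-sensing receptor gene Tlr8 (2.22), Gpr137b (2.06), the C-type lectin receptor gene Clec4d (2.05), the proton pump subunit gene Atp6v0d2 (2.01), the cytokine gene Il1a (1.96) and the receptor tyrosine kinase gene Mertk (1.96). The value of Gpr137b is uncertain because a near-identical pseudogene, chosen here after its value was seen, gave 1.84 for Gpr137b-ps.

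Mpo, which encodes myeloperoxidase of the granules of granulocyte and monocyte progenitors, showed the largest fall. Its intensity was 762 ± 32.1 with vehicle and 124 ± 11.2 with the inhibitor (SD, n = 3 each), a log2 fold change of -2.62 ± 0.08 (SE). The interferon-inducible genes Rtp4, Oasl2 and Cmpk2 fell by 1.80, 1.49 and 1.21 on the log2 scale. The sphingosine-1-phosphate receptor gene S1pr3 fell by 1.43, the small nucleolar RNA gene Snora21 by 1.31 and the actin-binding protein gene Nebl by 1.08. Another probe set of Nebl had a log2 fold change of -0.30 and did not pass the threshold when probe sets were tested singly (adjusted p = 0.0901 by limma). Smaller falls were those of Snord33 (log2 fold change -0.95), Rnu5g (-0.94), the carboxylesterase gene Ces2g (-0.91), the glutamate transporter gene Slc1a3 (-0.90) and the cytotoxic granule gene Nkg7 (-0.85). Rnu5g lay near the floor, with 1 of its 6 arrays at it, and did not pass with a floor of 32 (adjusted p = 0.573).

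**Figure D1:**
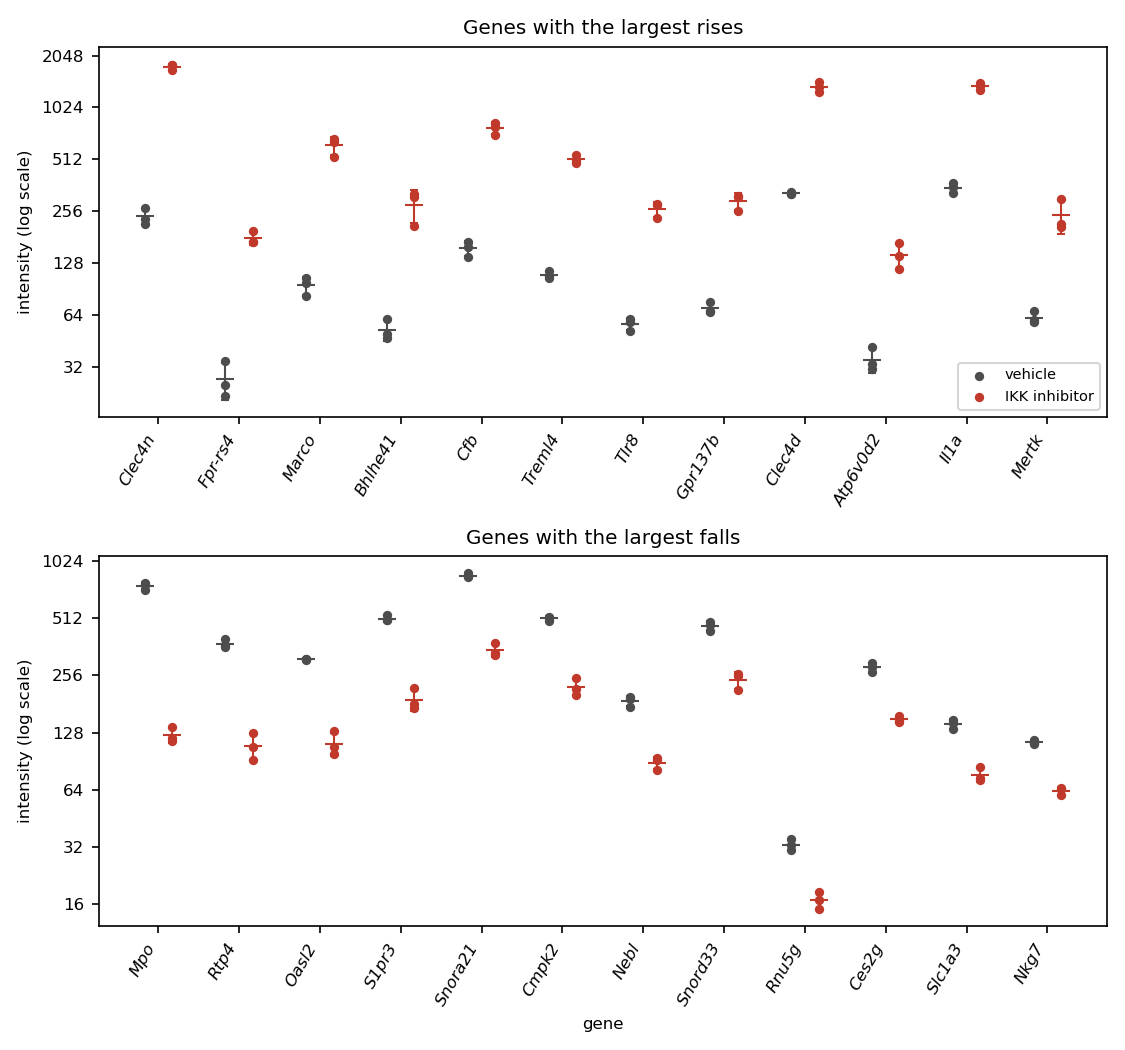
Deposited intensity on a logarithmic axis for the 12 genes with the largest rises (top) and the 12 with the largest falls (bottom); points are single arrays, horizontal bars the mean and vertical bars the SD of the 3 arrays of a group. By the rule that chose these 24 genes, all 3 arrays of a group lie above the 3 of the other, as for Clec4n, whose means were 238 and 1762.

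Of 19847 genes tested with limma, 2749 (13.9%) passed a Benjamini-Hochberg adjusted p of 0.05, 1409 of them higher and 1340 lower with the inhibitor. Most changes were small. Of the 2749 genes, 2353 (85.6%) changed by less than 1.5-fold, and the median absolute log2 fold change was 0.33. Changes of at least 2-fold were found for 137 genes, of which 130 were higher. The 7 that were lower were Mpo, Rtp4, Oasl2, S1pr3, Snora21, Cmpk2 and Nebl. In 6525 (32.9%) of the 19847 genes the 3 arrays of a group lay above the 3 of the other, an arrangement that chance gives in 10% of genes. The count fell when any array but inhibitor array 2 was left out, so the drop was not tied to a particular array. The share of higher calls rose whichever array was left out. With all arrays kept, an adjusted p under 0.01 gave 984 calls, 67.3% of them higher. The balance therefore also shifted with a stricter threshold alone. The count was 1567 without vehicle array 1, 1184 without vehicle array 2, 1219 without vehicle array 3 and 1273 without inhibitor array 1, whereas the count of 2-fold changes stayed between 131 and 139 when any array was left out. Without vehicle arrays 1, 2 and 3 and inhibitor array 1, 885, 788, 800 and 827 genes were called higher and 682, 396, 419 and 446 lower, and without inhibitor array 3 there were 775 lower. With quantile normalization 1332 were higher and 1597 lower, and with median centring 885 and 934.

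HOXA genes and their cofactors, the best known targets of MLL fusion proteins, did not pass the test as a group. Of 13 members tested, 12 did not pass the threshold. Hoxa9 had intensities of 1935 ± 47.0 with vehicle and 1791 ± 35.1 with the inhibitor (SD, n = 3 each) and a log2 fold change of -0.11 (95% interval -0.23 to 0.0016), and it was called lower with an intensity trend and robust prior (adjusted p = 0.0269). For Hoxa10 the log2 fold change was 0.01 (-0.13 to 0.15), for Meis1 0.05 (-0.08 to 0.19), for Hoxa7 -0.06 and for Pbx3 0.11, and these 4 did not pass. Hoxa3 was the single member called, with a fall of 0.27 on the log2 scale and an adjusted p of 0.0317 by limma, and it was also the single call when adjusted over the list alone. Its adjusted p was 0.0803 without vehicle array 1, 0.118 without vehicle array 2, 0.0911 without vehicle array 3, 0.0629 without inhibitor array 2, 0.0919 without inhibitor array 3 and 0.0763 with a replicate block. In limma's camera test, which sets a list against all other genes, the adjusted p of the HOXA list was 0.807 over the 32 lists. The median log2 fold change of the list was 0.01, its mean was -0.0065 and the test pointed down, so the signs differ. The median was -0.02 when each array was centred on its own median.

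Other MLL fusion target genes moved both ways. Of 23 tested, 2 were higher and 2 lower, against 3 and 2 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.725). The adhesion receptor gene Cd44 rose by 0.34 and Zeb2 by 0.29 on the log2 scale. The transcriptional repressor gene Gfi1 fell by 0.34. Sox4 fell by 0.33, with a limma adjusted p that was 0.0278 over all arrays and 0.101, 0.0964, 0.0985, 0.0506 and 0.0547 without vehicle arrays 2 and 3 and inhibitor arrays 1, 2 and 3. The Zeb2 call did not hold when each array was centred on its median (adjusted p = 0.0717). Myb (-0.09), Mef2c (-0.07), Cdk6 (-0.07), Flt3 (-0.05) and Bcl2 (0.16) did not pass. With an intensity trend and robust prior Myb and Bcl2 were called (adjusted p = 0.0256 and 0.0276), and Bcl2 also above the median intensity (0.0249), with array weights (0.0233) and with a floor of 64 (0.0396). Genes of the MLL complex and its elongation cofactors shifted slightly down, with a median log2 fold change of -0.09 over 31 members and a camera adjusted p of 0.00868, or adjusted p = 0.316 with an estimated correlation between genes. There, 1 member was higher and 4 were lower, against 1 and 5 adjusted over the list alone. Kmt2a rose by 0.35 on the log2 scale (adjusted p = 0.0175). Whether its probe set also reads the fusion transcript is not known here. Mllt10 had a log2 fold change of -0.04 and did not pass. Psip1 (-0.27), Ctr9 (-0.22), Kdm1a (-0.23) and Wdr5 (-0.19, named after its value was seen) were the members called lower. Of these 5 calls, 1 was left without vehicle array 1, none without vehicle arrays 2 or 3 or inhibitor array 1, and 2 without inhibitor array 3. The Kmt2a call was lost without vehicle arrays 1, 2 and 3 and inhibitor array 1, at adjusted p = 0.0583, 0.0574, 0.0726 and 0.057, and with a replicate block (0.0558). That block also ended the calls of Psip1, Ctr9 and Kdm1a (0.0647, 0.0746 and 0.0739), as did centring each array on its median (0.0577, 0.0669 and 0.0974). Beside the MLL complex list, monocyte and macrophage markers had a median of 0.76.

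NF-kB target genes were on balance higher with the IKK inhibitor, not lower. Of 53 members tested, 28 were higher and 2 lower, against 33 and 3 adjusted over the list alone, and the median log2 fold change was 0.29. In the camera test the adjusted p was 1.32e-13, and adjusted p = 0.0662 with an estimated correlation. Cytokine and chemokine genes were among those that rose, with log2 fold changes of 1.96 ± 0.07 for Il1a, 1.57 ± 0.07 for Ccl2 and 1.06 ± 0.05 for Cxcl2 (SE). Tlr2, a receptor for bacterial lipoproteins, rose by 0.98 ± 0.04. Among genes that encode the pathway's own inhibitors and subunits, Nfkbia (IkB alpha) rose by 0.36 ± 0.05, Tnfaip3 (the deubiquitinase A20) by 0.46 ± 0.05 and Nfkb2 by 0.49 ± 0.06. Relb rose by 0.29 (adjusted p = 0.017) and Birc3 by 0.45 (adjusted p = 0.0137), both by limma. The Relb call was lost without vehicle arrays 1 and 3 and inhibitor arrays 1 and 3 (adjusted p = 0.06, 0.0665, 0.0712 and 0.0507) and when each array was centred on its median (0.0718) or a replicate block was used (0.0607), the Birc3 call without vehicle arrays 1 and 2 and inhibitor array 1 (0.0507, 0.0574 and 0.0541). The 2 members called lower were Pim1 (log2 fold change -0.50) and, named after its value was seen, Ptgs2 (-0.33), whose call was lost without vehicle arrays 2 and 3, where 1 member was called lower. The median log2 fold change of monocyte and macrophage markers in the same cells was 0.76.

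**Figure D2:**
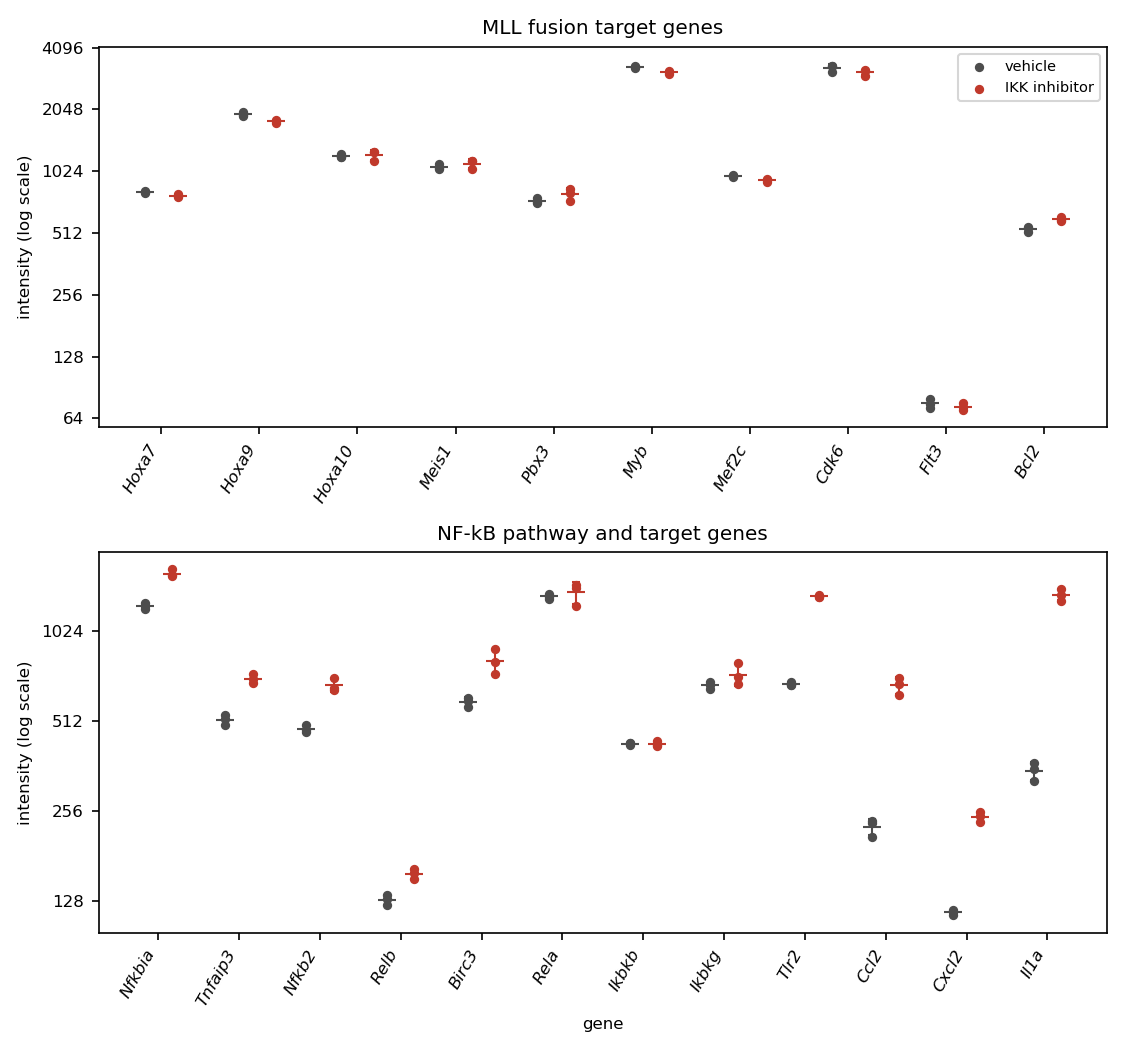
Deposited intensity on a logarithmic axis for 10 MLL fusion target genes (top) and 12 genes of the NF-kB pathway and its targets (bottom); points are single arrays, horizontal bars the mean and vertical bars the SD of the 3 arrays of a group. Hoxa9 means were 1935 and 1791, close together, whereas Il1a means were 350.2 and 1358.

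Genes for the signalling components upstream of NF-kB did not pass camera as a list, but they passed limma's fry test, pointing up (adjusted p = 0.00295). Of 24 tested, 3 were higher and 1 was lower, the same counts as when adjusted over the list alone, with a camera adjusted p of 0.264. The tumor necrosis factor receptor gene Tnfrsf1b rose by 0.60 and the IKK-related kinase gene Ikbke by 0.52 on the log2 scale. Malt1 (0.22) and Rbck1 (-0.22) were called over all arrays, Malt1 in none and Rbck1 in 1 of the 6 settings that leave out an array, and neither with median centring (adjusted p = 0.217 and 0.107) or a replicate block (0.0886 and 0.0794). Ikbkb, which encodes the kinase IKK beta, had mean intensities of 430.9 and 430.0, and neither it, Ikbkg (0.11) nor Rela (0.04) passed. Nfkb1 and Chuk are not analysed here.

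Monocyte and macrophage markers were the list with the strongest shift. Of 31 members tested, 23 were higher and none lower, against 24 and none adjusted over the list alone, with a median log2 fold change of 0.76. Against all other genes, the camera adjusted p was 7.5e-20, and adjusted p = 0.0652 with an estimated correlation. Gpnmb rose from an intensity of 952 to 3276, a log2 fold change of 1.78 ± 0.05, and Adgre1 (the macrophage antigen F4/80) by 1.43 ± 0.06 (SE). The receptor for macrophage colony-stimulating factor, Csf1r, rose by 1.23 ± 0.05, the integrin gene Itgam (CD11b) by 0.69 ± 0.05 and the lipopolysaccharide co-receptor gene Cd14 by 0.76 ± 0.07. The 8 members that did not pass included the complement genes C1qa (0.07), C1qb (-0.04) and C1qc (-0.03), named after their values were seen.

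Neutrophil granule and maturation genes moved both ways, with 12 of 26 higher and 4 lower, against 14 and 4 adjusted over the list alone. The median log2 fold change was 0.20, beside 0.76 for monocyte and macrophage markers. By camera the adjusted p was 0.0035, and adjusted p = 0.177 with an estimated correlation. Mgst1 rose by 0.95, the chitinase-like gene Chil3 by 0.91 and the secondary granule gene Ngp by 0.74 on the log2 scale, while Mpo fell by 2.62. The other members called lower were Ms4a3 (-0.56), Prtn3 (-0.28) and Elane (-0.24, called in 1 of the 6 settings that leave out an array), genes of early granulocyte and monocyte progenitors, named after their values were seen. Stem and progenitor cell genes did not pass camera (adjusted p = 0.616), with 4 of 20 higher and 3 lower, the same as when adjusted over the list alone. Procr rose by 0.54, Cd93 by 0.40 and the immediate early gene Egr1 by 0.77. Kit, the stem cell factor receptor gene, fell by 0.54 (adjusted p = 0.0189 by limma), and Lin28b by 0.50, a dim gene not called with a floor of 64 (adjusted p = 0.227). No member was called lower without vehicle array 2 or 3 or inhibitor array 1. The Kit adjusted p was 0.0504, 0.0733 and 0.0738 without vehicle arrays 1, 2 and 3 and 0.0625 without inhibitor array 1.

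Lists of markers of other blood and stromal cell types did not pass camera over all 6 arrays. Of 13 T cell and 11 erythroid markers none passed, over all genes or adjusted over the list alone, and the camera adjusted p was 0.674 and 0.636. Of 14 B cell markers 2 were higher, Cd22 (log2 fold change 0.79) and Blnk (0.32, not with a floor of 64, where adjusted p = 0.0565), and Igll1 was lower (-0.74), for a list adjusted p of 0.667. Of 15 mast cell and basophil markers 2 were lower, Kit and Hdc (-0.31, the sole call without vehicle arrays 1, 2 and 3 or inhibitor array 1), with a list adjusted p of 0.124, and 0.0417 without vehicle array 2. Of 10 megakaryocyte markers Vwf was higher (0.42) and Gp9 lower (-0.33, adjusted p = 0.0456 by limma, 0.0549 with quantile normalization and 0.0786 with a replicate block, called in 1 of the 6 settings that leave out an array), with a list adjusted p of 0.807. Among 14 dendritic cell markers, Itgax was higher (0.41, but adjusted p = 0.0613 without vehicle array 2, 0.0536 without inhibitor array 3 and 0.0539 with a replicate block), with a list adjusted p of 0.444. Of 15 fibroblast and stromal markers, Acta2 (0.77) and Pdpn (0.42) were higher, with a list adjusted p of 0.264. Of 8 MHC class II genes, Cd74, the invariant chain gene, was higher (1.07), and H2-Ob was lower (-0.26, called without inhibitor array 3 but in no other setting that leaves out an array, with adjusted p = 0.0512 with median centring and 0.0687 with a replicate block), with a list adjusted p of 0.994. Adjusted over the list alone the counts of these 6 last lists were the same. The MHC class II median was 0.02, while camera pointed down, so the signs differ. Medians of the erythroid, megakaryocyte, stromal and MHC class II lists changed sign with the scaling of the arrays, so no direction is given for them.

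Interferon-stimulated genes fell. Of 31 members tested, 18 were lower and 1 was higher, against 21 and 1 adjusted over the list alone, with a median log2 fold change of -0.31. Camera gave an adjusted p of 1.87e-10, and adjusted p = 0.13 with an estimated correlation. Rtp4 fell by 1.80 ± 0.12, Oasl2 by 1.49 ± 0.10, Cmpk2 by 1.21 ± 0.08 and Irf9, a subunit of the interferon-activated transcription factor, by 0.62 ± 0.07 (SE). The member called higher was Parp14 (0.33), named after its value was seen, and it was not called in any setting that left out an array. Calls of lower members numbered 12, 10 and 10 without vehicle arrays 1, 2 and 3 and 11 without inhibitor array 1. Monocyte and macrophage markers had a median of 0.76 in the same comparison.

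Genes of MYC-driven growth and ribosome biogenesis fell by small amounts. Of 44 tested, 31 were lower and none higher, against 34 and none adjusted over the list alone, with a median log2 fold change of -0.28. By camera the adjusted p was 2.73e-18, and adjusted p = 0.0652 with an estimated correlation. Myc fell by 0.35 ± 0.05, from an intensity of 2381 to 1869. Odc1, the rate-limiting enzyme of polyamine synthesis, fell by 0.44 ± 0.05, Rrp12 by 0.42 ± 0.05 and the RNA polymerase I subunit gene Polr1a by 0.37 ± 0.05 (SE). Calls numbered 12 and 15 without vehicle arrays 2 and 3 and 15 without inhibitor array 1. In the same cells 23 of 31 monocyte and macrophage markers were higher, with a median of 0.76.

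Genes of the cell cycle shifted down by still smaller amounts. Of 34 genes of G1/S and DNA replication 16 were lower and none higher, against 22 and none adjusted over the list alone, with a median log2 fold change of -0.19. In the camera test the adjusted p was 5.49e-09, and adjusted p = 0.224 with an estimated correlation. Fen1, a nuclease of DNA replication, fell by 0.34 ± 0.05 (SE). Of 37 genes of G2/M and mitosis 9 were lower and 1 was higher, against 17 and 2 adjusted over the list alone. Their median was -0.14, with a camera adjusted p of 6.21e-06, and adjusted p = 0.338 with an estimated correlation. The member called higher was Cdc25b (0.24), named after its value was seen, and it was not called in any of the 6 settings that leave out an array. Cenpa, a centromeric histone gene, had a log2 fold change of -0.42 (adjusted p = 0.018 by limma), a call lost without vehicle arrays 1, 2 and 3 and inhibitor array 1 (adjusted p = 0.0602, 0.0622, 0.0709 and 0.0631). Its log2 fold change in these settings was -0.42, -0.44, -0.41 and -0.43, so the call was lost with little change in the fitted fall. Many other calls in both lists were also lost when an array was left out, but both lists passed camera whichever array was left out. Without vehicle arrays 1, 2 and 3 and inhibitor array 1, calls of lower G1/S genes numbered 7, 2, 1 and 6, and those of lower G2/M genes 1, 0, 0 and 1; without inhibitor array 3 there were 3 in the G2/M list. Both moved beside monocyte and macrophage markers (median 0.76).

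NRF2 target genes of the oxidative stress response rose. Of 23 tested, 16 were higher and none lower, against 19 and none adjusted over the list alone, with a median log2 fold change of 0.36. Against all other genes, the camera adjusted p was 5.67e-14, and adjusted p = 0.0724 with an estimated correlation. Hmox1, the inducible heme oxygenase, rose from an intensity of 919 to 3377, a log2 fold change of 1.88 ± 0.06. The biliverdin reductase gene Blvrb rose by 1.12 ± 0.05, the cystine transporter gene Slc7a11 by 0.98 ± 0.05 and Srxn1 by 0.77 ± 0.06 (SE). Immediate early and ERK feedback genes were higher in 13 of 31 cases and lower in 1, Myc, against 14 and 2 adjusted over the list alone. Their median was 0.19, with a camera adjusted p of 9.28e-06, and adjusted p = 0.0652 with an estimated correlation. Dusp6, a phosphatase that acts on ERK, rose by 1.19 ± 0.07, Fos by 1.15 ± 0.07, Klf6 by 1.10 ± 0.08 and Jun by 0.58 ± 0.05 (SE). Both lists moved beside monocyte and macrophage markers, whose median was 0.76.

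Stress and metabolic lists moved less. Amino acid stress genes driven by ATF4 were lower in 10 of 32 cases and higher in 2, against 17 and 3 adjusted over the list alone, with a median log2 fold change of -0.14. Camera gave an adjusted p of 0.000111, and adjusted p = 0.122 with an estimated correlation. Atf3 (1.24) and Slc7a11 were the members that rose, while Pck2 fell by 0.46 and the arginine transporter gene Slc7a3 by 0.62. Calls of lower members numbered 5, 3 and 3 without vehicle arrays 1, 2 and 3 and 3 without inhibitor array 1. Unfolded protein response genes had a median of -0.09 over 24 members (camera adjusted p = 0.0163, and adjusted p = 0.316 with an estimated correlation). Crebrf rose by 0.58, and Pdia6 and Creld2 fell by 0.37 each, against 1 higher and 4 lower adjusted over the list alone. The Creld2 call was lost without vehicle array 3 (adjusted p = 0.0519), and the list did not pass without that array (camera adjusted p = 0.0507). Of 20 cholesterol synthesis genes, 3 were lower, also adjusted over the list alone: Idi1 (-0.32), Fdps (-0.28) and Sqle (-0.23). Their median was -0.09 (camera adjusted p = 0.00993, and adjusted p = 0.309 with an estimated correlation), and without vehicle arrays 2 and 3 or inhibitor array 1 Idi1 alone was called. The Sqle call ended with median centring (adjusted p = 0.0931) and a replicate block (0.0879). The calls of the cholesterol, unfolded protein response and MLL complex lists ended when genes under the median intensity were left out (camera adjusted p = 0.0576, 0.0745 and 0.0567). The amino acid stress, unfolded protein response and cholesterol lists moved beside monocyte and macrophage markers (median 0.76).

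Genes of the BCL2 family and inhibitors of apoptosis were higher in 3 of 22 cases and lower in 1, also adjusted over the list alone, with a median log2 fold change of 0.10. By camera the adjusted p was 0.0353, and adjusted p = 0.200 with an estimated correlation. Mcl1, which protects from apoptosis, rose by 0.44, the pro-apoptotic Bcl2l11 (BIM) by 0.45 and Birc3 by 0.45, and the pro-apoptotic Bid fell by 0.29. The list did not pass without vehicle array 1 (camera adjusted p = 0.088) or inhibitor array 2 (0.169), when each array was centred on its median (0.0781), or with array weights, and it moved beside monocyte and macrophage markers (median 0.76). Targets of p53 were higher in 8 of 29 cases and lower in 1, also adjusted over the list alone, and the list missed the threshold of camera (adjusted p = 0.0556), which it passed without vehicle array 2 (0.0152), inhibitor array 1 (0.0293) or inhibitor array 3 (0.0382), with quantile normalization (0.0454) and with median centring (0.0437). Trp53inp2 rose by 0.81, the death receptor gene Fas by 0.76 and Trp53inp1 by 0.66. Without vehicle arrays 1 and 3 and inhibitor arrays 1 and 3, 5, 4, 5 and 4 members were called higher. The lower call over all arrays was that of Psrc1 (-0.24, named after its value was seen). No member was called lower without vehicle array 1, 2 or 3 or inhibitor array 1 or 3. Without inhibitor array 2, 1 member was called lower.

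Genes of the STAT5 and cytokine response did not pass as a list (camera adjusted p = 0.0981), but 8 of 21 were higher and 4 lower, against 8 and 5 adjusted over the list alone. The transcriptional repressor gene Bcl6 rose by 1.20, Id2 by 0.82 and the cytokine receptor gene Csf2rb2 by 0.56, and the kinase gene Pim1 fell by 0.50. Without vehicle array 2, 5 were called higher. In the glycolysis and hypoxia list (adjusted p = 0.0996) 4 of 28 were higher and 2 lower, against 7 and 2 adjusted over the list alone; Aldoc rose by 0.57 and Bnip3 by 0.46. Without vehicle arrays 1, 2 and 3 or inhibitor array 1, 2 were called higher in each case and 1, 0, 1 and 1 lower. Of 14 heat shock genes Fkbp4 (-0.24) and Stip1 (-0.19) were lower, also adjusted over the list alone, with a list adjusted p of 0.183; without vehicle arrays 1, 2 and 3 or inhibitor arrays 1 and 2, neither was called, nor with median centring (adjusted p = 0.0541 and 0.106) or a replicate block (0.0962 and 0.0899), and without inhibitor array 3 Fkbp4 alone was. Of 12 housekeeping genes Pgk1 was higher (0.19, adjusted p = 0.04 by limma), none adjusted over the list alone, with a list adjusted p of 0.346. The Pgk1 call held in 1 of the 6 settings that leave out an array, the one without inhibitor array 2, and in neither rescaling of the arrays. It was also lost with a replicate block (adjusted p = 0.096 by limma). The 2 mitochondrially encoded genes measured, ND3 (0.21) and COX2 (0.31), did not pass over all genes and both were higher adjusted over the list alone, with a list adjusted p of 0.0886, and 0.0479 without vehicle array 3. Both genes were called higher without inhibitor array 2 (adjusted p = 0.0468 and 0.0338), above the median intensity (0.017 and 0.0282), with an intensity trend (0.000658 and 0.0281) and with array weights (0.0196 and 0.0221). ND3 was also called above the 25th percentile of intensity (0.0377), with floors of 32 and 64 (0.046 and 0.0302) and with 16 added in place of a floor (0.0407).

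**Figure D3:**
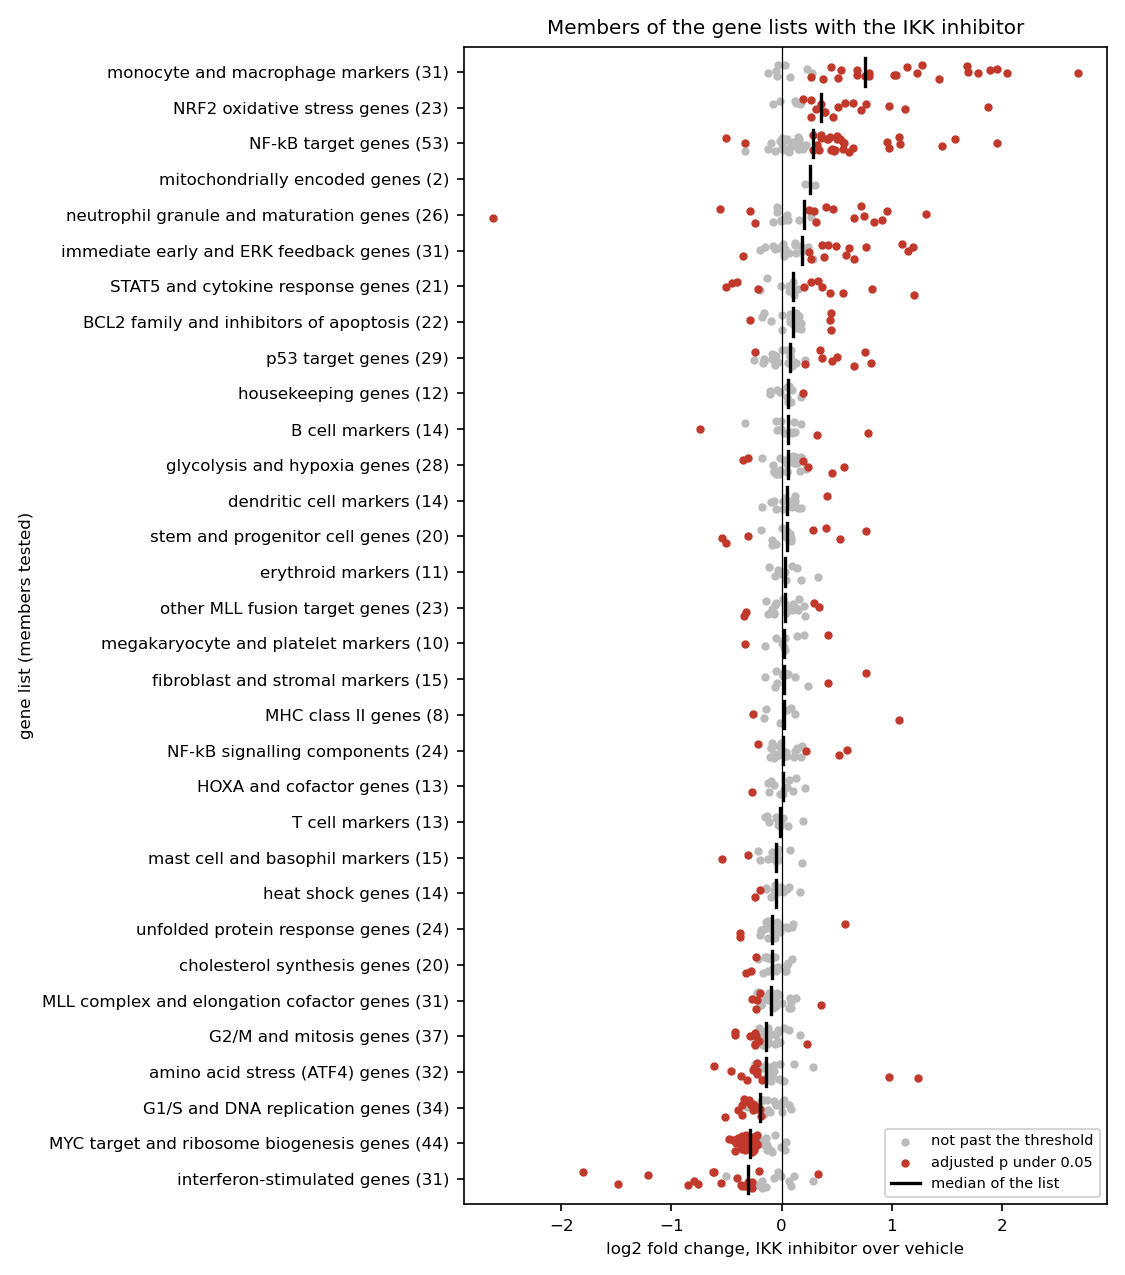
Log2 fold change of each member of the 32 gene lists, inhibitor over vehicle, with the number of members tested in brackets; red points passed an adjusted p of 0.05, grey points did not, and the black bar is the median of the list. Lists are ordered by their median, from 0.76 for monocyte and macrophage markers to -0.31 for interferon-stimulated genes.

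Of the 32 lists 14 passed camera, 6 up and 8 down, with a preset correlation of 0.01 between genes. With a correlation estimated from these arrays none passed, the lowest adjusted p being 0.0652. By limma's fry test, which asks whether the genes of a list move on balance one way without comparing them with other genes, 21 lists passed, including all 14. The lists that passed fry alone were p53, STAT5, glycolysis and hypoxia, NF-kB signalling, housekeeping and mitochondrial genes, all up, and heat shock genes, down. With the preset correlation, the other splits of the 6 arrays, which mix the groups and so keep part of the treatment difference, gave between 5 and 11 lists.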

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

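Probe sets that the annotation used here lists under no gene were left out of the gene results, and 191 of the 11176 tested were higher with the IKK inhibitor than with vehicle at an adjusted p under 0.05 (limma, every probe set tested singly), while 107 were lower. They were singled out because they lie outside the genes compared. Control probe sets of the array were not told apart from unnamed genes. A change among them therefore need not be that of a gene. The largest rises were those of probe set 10442098, with a log2 fold change of 2.49 and mean intensities of 164 and 920, and of probe set 10347335, with 2.47. The largest falls were those of probe set 10344404, with a log2 fold change of -1.38, and of probe set 10342910, with -1.34 and a mean of 15.3 in the inhibitor group, under the floor. No explanation was tested for them. Of 1598 probe sets listed under several genes, 24 were higher and 31 lower.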

How the results depend on the processing

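The floors other than 16 and the log2 of intensity plus 16 were chosen after the data were seen. Against 2749 changed genes, 1819 were called with each array centred on its median, 4199 with an intensity trend and robust prior, 4334 with array weights and 984 at an adjusted p under 0.01, the last by its stricter threshold; leaving out an array gave between 1184 (without vehicle array 2) and 2812 (without inhibitor array 2), with 1567, 1219, 1273 and 1841 without vehicle arrays 1 and 3 and inhibitor arrays 1 and 3. Fewer arrays leave fewer degrees of freedom; why the arrays differ was not tested, nor was the cause of the other shifts. The share of higher calls was 51.3%, against 45.5% with quantile normalization, 48.7% with median centring, 45.1% above the median intensity, 59.4% with a replicate block and 67.3% at an adjusted p under 0.01. Without vehicle arrays 1, 2 and 3 it was 56.5%, 66.6% and 65.6%, and without inhibitor arrays 1, 2 and 3 65.0%, 53.7% and 57.9%, so the direction with more calls depended on the setting. At least 2-fold changed 137 genes, 131 to 139 without an array, and 214 of all probe sets tested singly, where more items were tested. The 14 lists past camera became 0 with an estimated correlation, under which the NF-kB target list had an adjusted p of 0.0662; the cause was not tested. Without an array 13 to 16 lists passed, the NF-kB adjusted p lay between 7.02e-15 and 4.06e-10, and the HOXA adjusted p, past the threshold under no setting, between 0.617 and 0.992. No call of a named gene or list turned direction, but the balance of calls did, as did medians of some lists that did not pass.

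For 163 named genes under up to 18 settings, 2708 of 2904 results kept direction and side of the threshold, 154 lost and 42 gained the call. For the 30 lists other than NF-kB targets and HOXA, 525 of 540 did, 8 lost and 7 gained it. Median centring moved the median of all genes to -0.03 and quantile normalization to -0.02, from 0.0064. Without detection calls, signal over background is unknown, and the floor and the dim-gene filters are the limits tested.

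Samples share replicate numbers in their titles. Deviations of same-numbered arrays from their group means correlated at 0.24, 0.13 and -0.10 across genes, not above 0.1 for each pair, so the numbers were not taken to pair the samples. Only inhibitor array 1 correlated best with the vehicle array of its own number. With the number as a replicate block 1679 genes were called, 1628 of them shared with the 2749, and 19 of 118 named calls were lost.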

Other observations

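The gene families in this part were formed after the data were seen, and so were the tests of a lower share of leukemia cells, of scaling between arrays and of inflammatory members alone; adjusted p-values of families are by camera over these 14. Genes of the lysosome rose with the IKK inhibitor: 21 of 36 were higher and 1, Smpd1 (log2 fold change -0.29, called in 2 of the 6 settings that leave out an array), was lower. The family had a median of 0.249 (adjusted p = 4.23e-13, and adjusted p = 0.0435 with an estimated correlation). It was formed after the data were seen, so these arrays cannot test the proposal that lysosomal genes rose as a set. Adjusted p-values of the 14 families cannot be set beside those of the lists fixed before the data were examined. The acid lipase gene Lipa rose by 0.79, the saposin precursor gene Psap by 0.63, and the cathepsin genes Ctsb and Ctsd by 0.51 each. Of 21 V-ATPase genes, whose products acidify lysosomes, 10 were higher and none lower, with a median of 0.18 (adjusted p = 8.08e-08, and 0.0435 with an estimated correlation) and rises of 2.01 for Atp6v0d2 and 0.47 for Atp6v1g1. Leaving out vehicle arrays 1, 2 and 3 or inhibitor array 1 left 14, 12, 14 and 14 calls of higher lysosomal genes and 6 V-ATPase calls each. The monocyte and macrophage list moved with both, with a median of 0.76. Toll-like receptor genes were higher in 6 of 10 cases (median 0.47, adjusted p = 8.08e-08, and 0.0435 with an estimated correlation), among them Tlr8 (2.22), Tlr13 (1.48) and Tlr7 (1.12), and in 4 cases without vehicle array 1, 2 or 3 or inhibitor array 1. C-type lectin genes were higher in 12 of 33 cases (adjusted p = 1.70e-05, and 0.0763 with an estimated correlation), led by Clec4n (2.89), Clec4d (2.05) and Clec4b2 (1.89). Of 7 Fc receptor genes 3 were higher (adjusted p = 0.0166, and 0.156 with an estimated correlation), but 1 without vehicle array 1, 2 or 3 or inhibitor array 1, and of 4 formyl peptide receptor genes only Fpr-rs4 was (adjusted p = 0.076, but 0.0194 with median centring and 0.033 without inhibitor array 1). With median centring 13 lysosomal, 6 V-ATPase and 1 Fc receptor genes were called higher.

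Aminoacyl-tRNA synthetase genes fell: 9 of 18 were lower and none higher, with a median log2 fold change of -0.19 (adjusted p = 6.88e-08, and 0.0435 with an estimated correlation). Lars fell by 0.43 and Vars by 0.32, and 2, 3 and 2 calls were left without vehicle arrays 2 and 3 and inhibitor array 1; without vehicle array 1 there were 6, and with median centring 5. Proteasome subunit genes shifted by a median of -0.10, with 4 of 39 lower (adjusted p = 0.000145, and 0.0586 with an estimated correlation); 1, 1, 0 and 1 calls were left without vehicle arrays 1, 2 and 3 and inhibitor array 1, and 2 without inhibitor array 3, and 1 with median centring. Without inhibitor array 2 there was also 1 called higher. Of 60 ribosomal protein genes 4 were lower (adjusted p = 0.353, but 0.0336 without inhibitor array 3, pointing down), Rpl12 by the most at -0.72, with 1 call left without vehicle array 1, 2 or 3 or inhibitor array 1. Of 275 microRNA genes 9 were higher and 7 lower (adjusted p = 0.496). These counts were 4 and 3, 3 and 1, and 9 and 1 without vehicle arrays 1, 2 and 3, and 5 and 1, and 3 and 5 without inhibitor arrays 1 and 3. Beside the families that fell, monocyte and macrophage markers had a median of 0.76. The medians of the ribosomal and microRNA families changed sign with the scaling of the arrays or the array left out.

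The rise of monocyte and macrophage markers was set against a lower share of leukemia cells. That would raise markers of other cell types alike only if such cells were present. The highest median of 5 lists of other cell types was 0.0553 for B cells, far below 0.76, so these lists did not rise alike. This cannot decide the question, because cultures of a cell line may hold no such cells. A gain of monocytes alone would also leave these lists unchanged. The 26 members at or above the table's median intensity had a median of 0.775, which argues against noise of dim probe sets. Macrophages mixed into the treated cultures stay open: C1qa, C1qb, C1qc, Apoe, Mrc1 and Adgre1 had a median of 0.0367 with an SE of 0.29, too wide to decide, and as a family an adjusted p of 0.0785, but 0.0364 with median centring and 0.0365 without vehicle array 3, pointing up; Adgre1 rose by 1.43 and Mrc1 by 0.38 (called in 1 of the 6 settings that leave out an array), and Apoe and the C1q genes did not pass. All of these genes but Apoe also belong to the monocyte and macrophage list, so the test reuses values of the pattern it was to explain. An effect of the inhibitor on the leukemia cells themselves stays open too and was not tested, since it needs counts or markers of single cells, which these arrays do not give.

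The rise of NF-kB target genes is opposite to the fall that blocking IKK would give, and its list test did not pass with an estimated correlation (adjusted p = 0.0662; 2.70e-15 to 4.06e-10 under the other settings of camera). Scaling between arrays as the whole cause is argued against by the list's median, 0.29 as deposited, 0.281 with quantile normalization and 0.256 with median centring (SE 0.08). A rise of inflammatory members alone was set against 14 core pathway regulators of the same list, 9 of them called higher. Their median was 0.359 (camera adjusted p = 5.78e-08, and 0.0763 with an estimated correlation). These regulators are part of the list and were picked after the data were seen, so their rise cannot test that explanation. It shows only that members classed here as regulators rose too. Whether these regulators are themselves expressed more in monocytes was not tested, so a rise of monocyte-expressed members stays open. Whether the compound blocked IKK in these cells at the time of harvest was not measured, so the cause stays open, and no biological explanation was tested.

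Small nucleolar RNA genes fell, with 30 of 51 lower, none higher and a median log2 fold change of -0.36 (adjusted p = 1.59e-16, and 0.0435 with an estimated correlation), and 19, 15, 16 and 14 calls were left without vehicle arrays 1, 2 and 3 and inhibitor array 1. The 36 members at or above the table's median intensity had a median of -0.359, which argues against noise of dim probe sets. A general loss of small RNA stays open. The 78 bright microRNA genes had a median of 0.00721, which the bound set in advance took as evidence against such a loss, but their probe sets may read longer host transcripts. The 7 small nuclear and Y RNA genes had a median of -0.21 with a wide SE of 0.17, and 2 of the 7 were called lower. Their camera adjusted p was 0.0156, and 0.156 with an estimated correlation. Their fall goes with a loss, but only weakly. Monocyte and macrophage markers had a median of 0.76 beside this fall. Lower transcription of the host genes was not tested, since hosts were not matched to snoRNA genes; of 2 classes that hold hosts, 60 ribosomal protein genes had a median of -0.0022 (SE 0.02; -0.0341 without inhibitor array 3, where they passed camera), and the MYC target and ribosome biogenesis list one of -0.28.

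With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Only the real split, 1 of the 10, gave as many changed genes (2749, highest other 0), as many 2-fold changes (137, highest other 0), as small a p for the NF-kB list (13.8 as -log10, highest other 7.11) and as many lists (14, highest other 11). For the HOXA list 9 splits gave as small a p (0.107 as -log10, highest other 0.756). The other splits mix both groups and keep part of the treatment difference, so their 5 to 11 lists are not what chance alone would give.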
